A study of Homo sapiens with 20 samples.

How the data were processed

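RNA of THLE-3 cells was measured on 20 oligonucleotide arrays of the Affymetrix human HG-U133 design, array A, which reads most human protein-coding genes of its time through 1 or more probe sets each. THLE-3 is an established line of adult human liver epithelial cells immortalised with SV40 large T antigen. Per the labels, cells were in medium with 0.1 mM leucine (low) or 2.0 mM leucine (high) and were taken at 0, 30, 60, 120 or 480 min. Each of the 10 groups holds 1 array from a first experiment and 1 from a second experiment, as the labels call the replicates. The labels do not say how the cells were kept before 0 min or whether an experiment stands for a separate culture, so p-values measure only the spread between these samples, which can be technical.

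The deposited values were linear probe set intensity values, in arbitrary units, for 22215 probe sets without control probe sets. The method by which the authors summarised and scaled the arrays is not given in the sources used here. The values ran from 0 to 26170, with 16 exact zeros, and the array medians lay between 433.2 and 492.9. The 2% trimmed means of the arrays ran from 629.9 to 705.1, a spread of 11.9% that was above the 5% limit set for taking them as already scaled. For arrays the number of samples limits the precision; no read depth applies.

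A pseudocount of 165.2, the median over arrays of the 10th percentile, was added before taking log2, and the arrays were then quantile normalized. The pseudocount pulls the changes of weak probe sets towards 0. Probe sets with a mean log2 value at or above the 40th percentile were kept, which left 13329 probe sets and 8280 genes with a symbol of their own. Of all probe sets, 19065 carried 1 symbol, 1043 carried several and 2107 carried none, and only those with 1 symbol were named. Where a gene had several probe sets, the one with the highest mean was taken.

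All comparisons were fitted over all 20 arrays with limma 3.58.1 in R 4.3.3, with 1 mean per group, moderated variances with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over the probe sets kept. The threshold was an adjusted p under 0.05. The comparisons were high against low leucine averaged over the 5 times and at each time, the change of that difference over time, and each later time against 0 min averaged over both leucine levels. The model fixed at the start had no term for the experiment and 10 residual degrees of freedom, and is called the unblocked fit. The labels give each array an experiment, and the arrays differed strongly by it, so every comparison was also fitted with the experiment as a fixed term and 9 residual degrees of freedom, which is called the blocked fit. In both fits the estimated change is the same and the error differs. Each ± is the standard error of the change in the fit named with it, with n = 2 arrays per group. Recovery of planted changes was tested on simulated data at 480 min. Noise was drawn independently with the residual spread of the blocked fit, plus the same shift between experiments at all times. This is the model of the blocked fit, so the test favours it and cannot choose between the fits. In the real data 96 probe sets changed differently in the 2 experiments from 0 to 60 min. This came from a separate fit with a mean for each experiment and time plus a term for leucine level. Of 100 probe sets moved by 0.5 on the log2 scale between leucine levels, the unblocked fit called 50 and the blocked fit 94, and of 100 moved by 1 they called 86 and 99. The blocked fit then also called 12 unchanged probe sets.

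Gene lists were compared with all other genes by camera of limma with a preset correlation of 0.01, and again with the correlation estimated from the data, adjusted over the 30 lists of 824 genes. Some genes are on more than 1 list, so calls of different lists are not independent. Members past the threshold were counted over all probe sets and also adjusted over the list alone. A range in brackets after a median over genes is a 95% interval from 2000 resamples of the genes. It does not resample arrays, so it does not measure the spread between samples. Named genes were, per comparison and fit, the up to 12 largest rises and up to 12 largest falls past the threshold, the 5 smallest p-values where fewer than 5 genes passed, up to 4 list members with the smallest p, and ASNS, DDIT3, TRIB3, ATF3, SLC7A11, BCAT1, BCAT2, SLC7A5 and ATF4 whatever their p. The comparisons, the unblocked model, the lists, this rule per comparison and a first set of alternatives were fixed before the data were examined. The rule as fixed did not provide for a second fit. Its use on the blocked fit and the ranking of list members by the blocked p went beyond it. The alternatives were a pseudocount 4 times larger or smaller, values as deposited, median centring, no filter or one at the 60th percentile, 1 probe set per gene, variances without the trend, array weights, the blocked fit, an additive model, single experiments or leucine levels, and each array left out in turn. The blocked fit combined with each of these, fits without the 0 min arrays, and a 30 min reference were added after seeing the data. Python 3.11.15 with matplotlib 3.10.9 drew the figures.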

Results

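The series asked how leucine supply changes gene expression in a cultured human liver line. Expression was measured in THLE-3 cells in 0.1 mM or 2.0 mM leucine at 0, 30, 60, 120 and 480 min, with 2 arrays in each of the 10 groups. Mean intensity per array ran from 761.8 to 862.6 units. The median of the array means was 787.2 in the first experiment and 848.3 in the second.

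Probe sets of some keratin and mesenchymal genes gave high signal and those of most hepatocyte genes did not, although probe affinity differs, so that ranks do not compare amounts of RNA. KRT18, a keratin of simple epithelia, lay at percentile 99.1 of all probe sets. VIM, the intermediate filament of mesenchymal and cultured cells, lay at 99.2, and SPARC, a matrix glycoprotein, at 98.6. ALB, which encodes serum albumin, lay at 9.92 and was removed by the filter. Of 20 hepatocyte markers on the array, 0 lay above the 90th percentile by mean signal, against 4 of 12 biliary and epithelial markers, all keratins, and 5 of 14 stellate and fibroblast markers. Most other epithelial markers lay low, with EPCAM at 10.8, CDH1 at 7.31, SOX9 at 24.3, SPP1 at 5.63, KRT14 at 19.2 and CLDN4 at 29.9. CLDN7 at 67.9 and KRT5 at 42.4 lay higher and were kept by the filter.

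The arrays separated by experiment more than by leucine or time. Correlations across probe sets, which are not independent replicates, ran from 0.970 to 0.996 within an experiment and from 0.911 to 0.939 between experiments. The first principal component held 71.8% of the variance and parted the 10 arrays of one experiment from those of the other. With the leucine and time groups in the model, 8270 of 13329 probe sets (62%) differed between experiments and 361 of them by more than 2-fold. The largest single differences were in ORAI2, a calcium channel subunit, higher in the second experiment by 2.74, and FAM174B, higher by 2.59. For the mean leucine difference the error was larger in the unblocked than in the blocked fit for 13044 of 13329 probe sets (97.9%), so results are given with both fits. In each comparison 666.4 probe sets would have an unadjusted p under 0.05 by chance. Several unblocked counts lay below this, with 102 for leucine at 60 min. An unblocked count of 0 calls therefore does not show that there was no effect.

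At 480 min, high leucine lowered genes of the amino acid response, the programme that cells turn on when amino acids are scarce. ATF4, the transcription factor at its centre, changed by -1.05 ± 0.13 (unblocked, adjusted p = 0.016; blocked 1.6e-06), from a mean intensity of 5030 in low to 2340 in high leucine. SLC7A11, the cystine and glutamate exchanger, changed by -1.32 ± 0.22 (unblocked, adjusted p = 0.035), CEBPG, a bZIP partner of ATF4, by -0.89 ± 0.12, and MTHFD2, a mitochondrial one-carbon enzyme, by -0.92 ± 0.13. The blocked fit added STC2, a secreted glycoprotein, at -1.28 ± 0.12 and TRIB3, a pseudokinase induced by ATF4, at -1.25 ± 0.11. It also added DDIT3, the stress transcription factor CHOP, at -0.87 ± 0.10, and SLC7A1, a cationic amino acid transporter, at -0.86 ± 0.06, although other SLC7A1 probe sets ran from 0.10 to -0.43. ASNS, which makes asparagine, fell by 0.43 ± 0.11 in the blocked fit (adjusted p = 0.032), with 0.55 in the unblocked fit.

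Of 35 measured members of the amino acid response list, 4 fell in the unblocked fit and 21 in the blocked fit, 0 rose in either, and adjusted over the list alone 17 and 27 fell. Its median change was -0.43, with -0.38 in the first experiment and -0.54 in the second (camera adjusted p = 6.5e-26). With an estimated correlation this list kept its call (adjusted p = 0.019 with an estimated correlation). Of 17 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 1 fell in the unblocked fit, and 9 fell and 1 rose in the blocked fit. Their median was -0.27 (camera adjusted p = 3.7e-12, and 0.019 with an estimated correlation). CARS1, the cysteine enzyme, fell by 0.77 ± 0.09 (unblocked, adjusted p = 0.011). SARS1 at -0.75 ± 0.07, AARS1 at -0.56 ± 0.05 and GARS1 at -0.79 ± 0.10 fell in the blocked fit. MTHFD2, PSAT1 at -0.60 ± 0.07 and SHMT2 at -0.52 ± 0.09 were the 3 of 17 polyamine, serine and one-carbon genes that fell in the blocked fit. The call of that list (adjusted p = 0.015, median -0.03, mean -0.15) was lost at adjusted p = 0.065 with an estimated correlation.

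**Figure D1:**
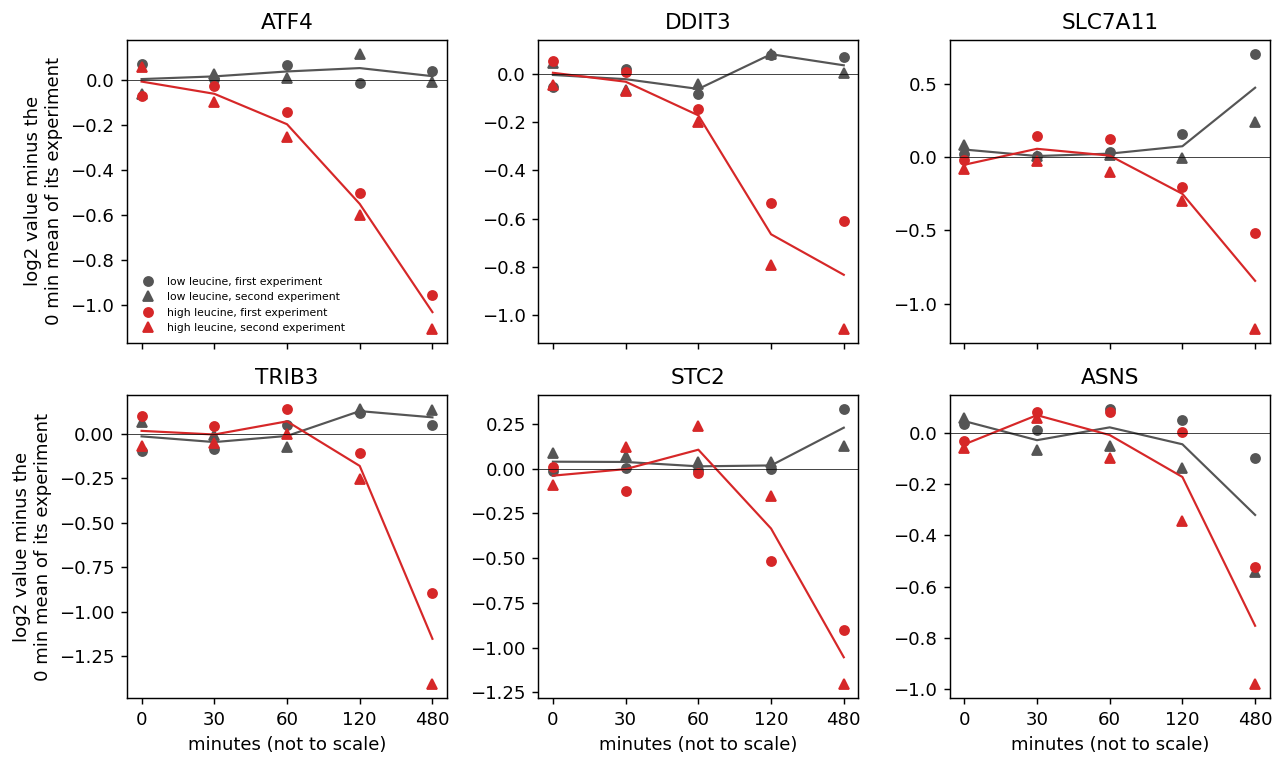
Log2 value of 6 amino acid response genes minus the mean of the 0 min arrays of the same experiment, against time in minutes; points are single arrays (n = 2 per group) and lines are group means. In high leucine ATF4 and DDIT3 lay below their 0 min level at 120 and 480 min, while ATF4 in low leucine differed from 0 min by 0.01 at 480 min.

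Single endoplasmic reticulum stress genes were among the falls in high leucine at 480 min, and single cytosolic chaperone and sterol genes among the rises. XBP1, a transcription factor of the unfolded protein response, fell by 0.64 ± 0.09 (unblocked, adjusted p = 0.016). Further falls with the block were HERPUD1 at -0.68 ± 0.09, DNAJB9 at -0.75 ± 0.12 and HSPA5, the main chaperone of the reticulum, at -0.51 ± 0.09, so that it called 5 of 21 list members lower and 0 higher. The list had a median of -0.13 and camera gave an adjusted p = 4.2e-05, but adjusted p = 0.055 with an estimated correlation, where the blocked fit gave 0.042. Of 15 cytosolic heat shock genes, 5 rose and 0 fell in the blocked fit, with a median of 0.20 (camera adjusted p = 4.6e-07, and 0.019 with an estimated correlation in the unblocked fit against 0.071 in the blocked one). HSPB1, a small heat shock protein, rose by 0.87 ± 0.09 (blocked, adjusted p = 3.9e-05; unblocked 0.056). HSPH1, of the Hsp110 family, rose by 0.48 ± 0.08 in the unblocked fit (adjusted p = 0.035). Of 19 cholesterol synthesis and uptake genes, 1 rose in the unblocked fit, 7 in the blocked fit and, adjusted over the list alone, 5 and 12, with 0 falling. The list median was 0.20 (camera adjusted p = 1.9e-07, and 0.022 with an estimated correlation). IDI1, which makes dimethylallyl diphosphate, rose by 0.59 ± 0.08 (unblocked, adjusted p = 0.016). MSMO1 at 0.68 ± 0.08, DHCR7 at 0.41 ± 0.07 and EBP at 0.40 ± 0.06, all sterol enzymes, rose in the blocked fit, and so did INSIG1, a sterol sensor partner, at 0.65 ± 0.16.

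Translation factors moved both ways, and their list passed camera with a median of -0.02 and a mean of -0.06 (adjusted p = 0.0033, and 0.022 with an estimated correlation; blocked 0.014, and adjusted p = 0.058 with an estimated correlation). In the blocked fit 6 of 37 fell and 1 rose. EIF3A changed by -0.48 ± 0.06 and EIF1 by -0.25 ± 0.05, while EIF4E, the cap-binding protein, rose by 0.58 ± 0.10 (adjusted p = 0.0044; unblocked 0.97). Other genes past the unblocked threshold were TUBA1A, an alpha tubulin, at 0.73 ± 0.10, HSPA2, a member of the Hsp70 family, at 0.46 ± 0.08, ABHD17A at 0.44 ± 0.07, the kinase PRP4K at 0.42 ± 0.06, CHPF2 at 0.41 ± 0.06 and DYNLL1, a dynein light chain, at 0.36 ± 0.05. TMEM14A at 0.36 ± 0.06, NSFL1C at 0.34 ± 0.06 and TMSB10, a thymosin, at 0.25 ± 0.04 also passed. Falls were GFPT1, the entry enzyme of hexosamine synthesis, at -0.89 ± 0.15, IFRD1 at -0.79 ± 0.12, HSPA9, the mitochondrial Hsp70, at -0.55 ± 0.08, PMAIP1, a pro-apoptotic BH3-only protein, at -0.50 ± 0.08, COPA, a coatomer subunit, at -0.49 ± 0.07 and TIMM9, a mitochondrial import chaperone, at -0.48 ± 0.07. Further blocked rises were LOXL1 at 0.64 ± 0.11, FADS2 and TUBB2A at 0.59, HSPE1 at 0.55 ± 0.08 and CD14 and DKK1 at 0.53. Further blocked falls were CAMTA2 at -1.14 ± 0.10, VEGFA, the endothelial growth factor, at -0.995 ± 0.14 and GDF15, a stress cytokine, at -0.83 ± 0.19. Other probe sets of VEGFA ran from -0.15 to -0.36, that of COPA was at -0.11, and 1 of NSFL1C was at 0.07.

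In total 36 probe sets of 28 genes passed at 480 min in the unblocked fit, 15 higher and 21 lower, and 886 had an unadjusted p under 0.05 where 666.4 would be expected by chance. The blocked fit called 545, with 330 higher and 215 lower, among them all 36. All genes named here moved the same way in both experiments. Most were named because they passed the threshold, which by itself makes a shared direction likely, so this is not separate evidence. Over all probe sets 63.3% had the same sign in both experiments. Of the nutrient genes fixed in advance, ATF3 at -0.42 ± 0.21, SLC7A5, a leucine transporter subunit, at -0.40 ± 0.21, BCAT1 at -0.09 ± 0.08 and BCAT2 at 0.26 ± 0.07, both leucine aminotransferases, did not pass in the blocked fit (adjusted p of 0.33, 0.36, 0.63 and 0.058). On values as deposited the unblocked count was 15, with array weights 20 and without the 0 min arrays 21. It fell to 0 without the second low leucine array at 480 min, where the blocked count without the second high leucine array was 131.

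Further camera calls at 480 min were lost with an estimated correlation, and the other lists did not pass. Cell cycle genes had a median of 0.10 (adjusted p = 0.0013, and adjusted p = 0.56 with an estimated correlation), proteasome genes 0.13 (6.9e-05 and 0.34), oxidative phosphorylation genes 0.07 (0.0026 and 0.37) and ribosome biogenesis genes -0.09 (0.00075 and 0.34). PCNA, the replication clamp, at 0.45 ± 0.07 and CCNA2, a cyclin, at 0.48 ± 0.08 rose in the blocked fit, and MCM7, a helicase subunit, fell by 0.30 ± 0.06. The fatty acid synthesis list, with a median of 0.07, passed in the blocked fit (adjusted p = 0.025, and 0.41 with an estimated correlation; unblocked 0.064). Lists that did not pass in either fit had medians of -0.03 for branched-chain amino acid catabolism, -0.02 for mTORC1 components, -0.02 for ribosomal proteins, -0.02 for glycolysis, -0.05 for insulin and fasting genes and -0.01 for immediate early genes. The same held for fatty acid oxidation at 0.00, NRF2 targets at 0.05, p53 targets at 0.00, autophagy and lysosome genes at -0.04, NF-kB genes at -0.05, interferon genes at -0.01, hypoxia genes at -0.02 and TGF-beta and matrix genes at 0.07. Markers of hepatocytes had a median of -0.05, of biliary epithelium -0.01, of stellate cells and fibroblasts 0.03 and of endothelium and blood cells -0.02. Single members moved in the blocked fit, with KRT19, a biliary keratin, at 0.52 ± 0.08 and TXNIP, a thioredoxin inhibitor induced by glucose, at -0.60 ± 0.10.

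Falls of amino acid response genes from 0 to 480 min were called in high leucine and not in low leucine. ATF4 changed by 0.01 ± 0.07 in low leucine and by -1.03 ± 0.07 in high leucine (blocked, adjusted p = 5.1e-07; unblocked 0.0039). TRIB3 changed by 0.11 ± 0.11 and -1.17 ± 0.11, DDIT3 by 0.04 ± 0.10 and -0.84 ± 0.10, and ASNS by -0.37 ± 0.11 and -0.71 ± 0.11. SLC7A11 differed from these with 0.42 ± 0.13 in low leucine (blocked, adjusted p = 0.13) and -0.79 ± 0.13 in high leucine. Of 35 list members, 0 rose and 0 fell in low leucine, and 24 fell in high leucine in the blocked fit, with medians of 0.03 and -0.57. The test of the difference between these changes is given with the results flagged for a closer look. There the list lost its call with an estimated correlation, and ASNS did not pass. Over all probe sets, low leucine gave 0 calls in the unblocked limma fit, with 734 at an unadjusted p under 0.05, and 31 in the blocked fit, where high leucine gave 229 and 2032.

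At 120 min a few genes differed between leucine levels. PMAIP1 fell by 0.61 ± 0.08 in high leucine (unblocked, adjusted p = 0.045; blocked 0.0016) and was the 1 probe set called in the unblocked fit. The blocked fit added ATF4 at -0.61 ± 0.07, DDIT3 at -0.75 ± 0.10 and 1 probe set of TXNIP at -0.56 ± 0.09, so that it called 4, all lower. The TXNIP probe set with the highest signal was at -0.40 and did not pass (blocked, adjusted p = 0.8), and the other was named after its value was seen. CHAC1, a glutathione-degrading enzyme induced by ATF4, was at -0.56 ± 0.11 and did not pass (blocked, adjusted p = 0.19). The change of the leucine difference from 0 to 120 min was not called for PMAIP1, ATF4 or DDIT3 in either fit. Across all probe sets the 120 min differences of the 2 experiments correlated at only 0.0422, with the same sign for 50.3%. The amino acid response list had a median of -0.13 (camera adjusted p = 7.9e-10, and adjusted p = 0.36 with an estimated correlation), with 2 of 35 falling in the blocked fit and, adjusted over the list alone, 6. In the blocked fit alone NF-kB genes at a median of -0.13 passed as well (adjusted p = 0.00012, and adjusted p = 0.45 with an estimated correlation), as did insulin and fasting genes at -0.09 (0.034 and 0.52), immediate early genes at -0.09 (0.031 and 0.93) and heat shock genes at 0.07 (0.039 and 0.93). The call of PMAIP1 was lost on values as deposited, with median centring, without a filter, with a larger pseudocount, without the 0 min arrays and in other alternatives, and it passed in 8 of 30. The unblocked count was 0 in 18 of the 20 fits that left out 1 array.

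At 30 and 60 min no single probe set passed the test between leucine levels. At 30 min limma called 0 probe sets in both fits, with 154 (unblocked) and 593 (blocked) at an unadjusted p under 0.05, both below the 666.4 expected by chance. The smallest p-values were those of ALG6, a glycosyltransferase, at -0.34 ± 0.06 and ZNF480, a zinc finger gene, at -0.34 ± 0.06 (blocked, adjusted p = 0.41 for both). Ribosomal proteins had a median of 0.04 at 30 min (camera adjusted p = 0.00089, and adjusted p = 0.96 with an estimated correlation). At 60 min limma again called 0 in both fits, with 102 and 419 at an unadjusted p under 0.05, and FBXO41 at -0.19 ± 0.05 and BMP2K at -0.20 ± 0.06 had the smallest unblocked p. ATF4 was at -0.08 ± 0.07 at 30 min and -0.24 ± 0.07 at 60 min, neither past the test.

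At 0 min the leucine levels differed only in the blocked fit. There RAD21, a cohesin subunit, was at -0.51 ± 0.09, AASDHPPT, a phosphopantetheinyl transferase, at -0.51 ± 0.08, PIK3C2A, a lipid kinase, at -0.46 ± 0.08, IFRD1 at -0.45 ± 0.08 and HTATSF1 at -0.44 ± 0.08. PRNP, the prion protein, was at -0.31 ± 0.06, and DCAF15 at 0.39 ± 0.07 and APOE, an apolipoprotein, at 0.25 ± 0.05 were higher. The blocked fit called 77 probe sets, 11 higher and 66 lower, while the unblocked limma fit called 0, with 862 at an unadjusted p under 0.05. For 19 genes with other probe sets, these had the same sign in 15 but changed by a median of 0.189 of the named ones, with RAD21 at 0.11, HTATSF1 at 0.04, PRNP at 0.00, AASDHPPT at -0.05 and IFRD1 at -0.23. The blocked count was 2 with array weights and 1 without the second low leucine array at 0 min. No list passed in either fit, and ATF4 was at -0.01 ± 0.07.

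Averaged over the 5 times, PMAIP1 fell by 0.28 ± 0.03 in high leucine and was the only probe set called in the unblocked fit (adjusted p = 0.038; blocked 0.00057). In the blocked fit ATF4 at -0.40 ± 0.03, DDIT3 at -0.35 ± 0.04, SLC7A11 at -0.34 ± 0.06, IFRD1 at -0.34 ± 0.04, STC2 at -0.33 ± 0.06, TRIB3 at -0.28 ± 0.05 and TXNIP at -0.27 ± 0.05 fell. HSPB1 at 0.24 ± 0.04 and ABHD17A at 0.14 ± 0.02 rose. The blocked fit called 23, with 3 higher and 20 lower, and the unblocked fit had 309 at an unadjusted p under 0.05. The blocked count was 0 with the additive model. Of 100 splits of the arrays, the real split included, 6 called as many with the block, so chance is not excluded. Of 30 lists, 7 passed camera in the unblocked fit and 2 of them with an estimated correlation. These were the amino acid response at a median of -0.13 (adjusted p = 3e-21, and 0.047 with an estimated correlation) and heat shock genes at 0.05 (1.2e-05 and 0.047; blocked, adjusted p = 0.15 with an estimated correlation). Synthetases at -0.06 had an adjusted p = 0.075 with an estimated correlation (blocked 0.035), cholesterol synthesis genes at 0.04 had 0.24, and endoplasmic reticulum stress, oxidative phosphorylation and proteasome genes had 0.46. The unblocked count was 0 with median centring, without a filter and in 18 of the 20 fits that left out 1 array.

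**Figure D2:**
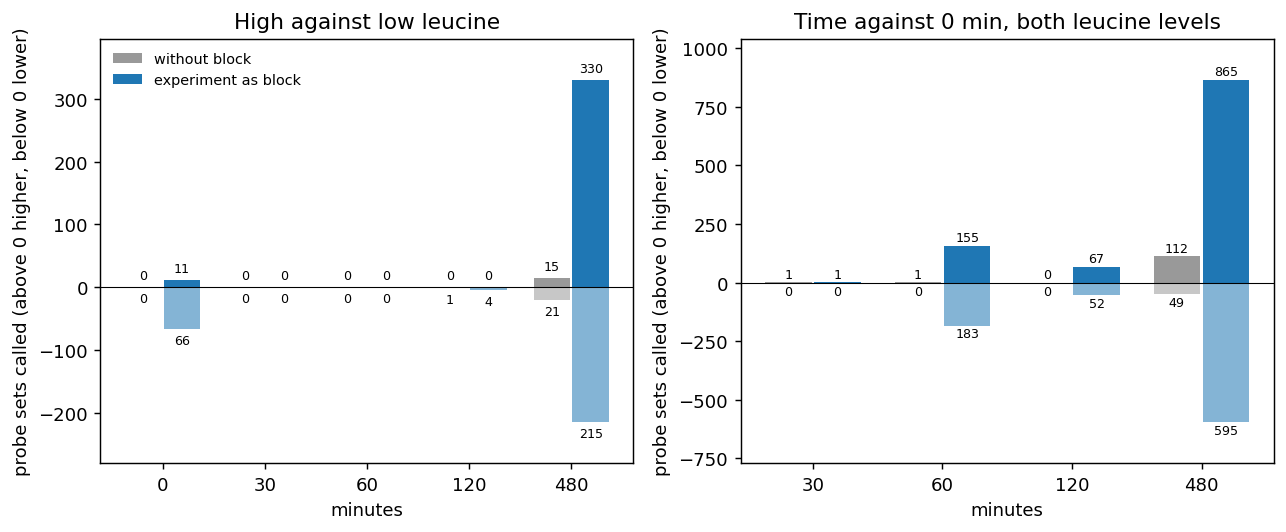
Probe sets called at an adjusted p under 0.05 for high against low leucine (left) and for time against 0 min (right), by time in minutes; bars above 0 count higher and bars below 0 lower probe sets, gray without and blue with the experiment as a block. The blocked fit called 545 at 480 min between leucine levels and 1460 for 480 against 0 min.

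Whether the leucine difference itself changed over time was tested with the interaction. With the block, 1 probe set of EIF4E was the only one whose difference changed from 0 to 120 min, by 0.75 ± 0.08 (adjusted p = 0.00087), and it was named after its value was seen. The EIF4E probe set with the highest signal, used elsewhere in the text, changed by 0.26 ± 0.14 and did not pass (adjusted p = 0.71). At 480 min ATF4 changed by -1.04 and CARS1 by -0.85 relative to 0 min (adjusted p = 8.2e-05 for both in the blocked fit, and 0.1 for ATF4 in the unblocked one). The unblocked limma fit called 0 probe sets over the 4 times together, with 492 at an unadjusted p under 0.05, and the blocked fit called 86. Against the 0 min difference the blocked fit called 43 at 30 min, 0 at 60 min, 1 at 120 min and 509 at 480 min. These counts also hold the 0 min difference of the blocked fit, and leucine at 30 min itself gave 0 calls. The unblocked fit called 0 at each, with 844, 465, 307 and 1038 at an unadjusted p under 0.05.

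The comparisons of later times with 0 min share the 0 min arrays and average both leucine levels. CCNL1, a cyclin of RNA processing, was the only probe set called at 30 min, at 0.35 ± 0.04 (unblocked, adjusted p = 0.029; blocked 0.0044), and the only one called at 60 min in the unblocked fit, at 0.37 ± 0.04 (adjusted p = 0.015; blocked 0.002). The immediate early list had a median of 0.16 at 30 min (camera adjusted p = 0.0038, and adjusted p = 0.95 with an estimated correlation). The list of branched-chain catabolism was at 0.06 (0.024, and adjusted p = 0.52 with an estimated correlation), and interferon genes at 0.04 passed in the blocked fit only (0.032, and adjusted p = 0.52 with an estimated correlation). The unblocked limma fit had 545 at an unadjusted p under 0.05 at 30 min, and its count was 0 on values as deposited and in 16 of the 20 fits that left out 1 array.

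At 60 min single immediate early genes, which respond within an hour to serum or stress, were among the rises, mainly in the second experiment. The call of their list was lost with an estimated correlation. EGR1, a zinc finger transcription factor, rose by 1.72 ± 0.42 (blocked, adjusted p = 0.047), with 0.29 in the first and 3.15 in the second experiment. CCN2, a matricellular growth factor, rose by 1.39 ± 0.33, IER3, a survival protein, by 0.99 ± 0.23, HES1, a Notch target, by 0.98 ± 0.25 and DUSP1, a MAP kinase phosphatase, by 0.83 ± 0.20, each with an adjusted p of 0.047 or 0.049. CXCL8 at 0.54 ± 0.11, GADD45A at 0.46 ± 0.11, CITED2 at 0.43 ± 0.10 and MCL1 at 0.39 ± 0.10 also rose, although 1 other MCL1 probe set was at -0.14. TXNIP fell by 0.35 ± 0.07, DELE1 by 0.33 ± 0.07 (its other probe set was at 0.13) and HOXD9 by 0.29 ± 0.05. Of 35 members of the immediate early list, 7 rose in the blocked fit and 25 adjusted over the list alone. Its median was 0.41, with 0.10 in the first experiment and 0.77 in the second (camera adjusted p = 2.2e-12, and adjusted p = 0.81 with an estimated correlation). Smaller shifts in p53 targets at 0.06 (0.031 and 0.98), NF-kB genes at 0.12 (0.028 and 0.98) and fatty acid synthesis genes at -0.10 (0.0079 and 0.28) also lost their calls with an estimated correlation. The blocked fit called 338 probe sets, 155 higher and 183 lower, where the unblocked fit had 1159 at an unadjusted p under 0.05. For 18 genes called with a change between 0.225 and 0.532 in size, other probe sets changed by a median of 0.315 (0.11 to 0.568) of the named ones, with the same sign for 14. The blocked count was 21 with array weights and 1 without the second low leucine array at 0 min.

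At 120 min CCN2 at 1.54 ± 0.33, EPHA2, a receptor tyrosine kinase, at 0.60 ± 0.12, TUBB2A, a beta tubulin, at 0.57 ± 0.10, ZFP36L2 at 0.41 ± 0.08 and JUND, an AP-1 subunit, at 0.33 ± 0.05 rose in the blocked fit. TXNIP at -0.42 ± 0.07, CHAC1 at -0.34 ± 0.07, TSC22D3, a glucocorticoid target, at -0.32 ± 0.06 and ATF4 at -0.25 ± 0.05 fell. The blocked fit called 119 probe sets, 67 higher and 52 lower, and the unblocked limma fit 0, with 902 at an unadjusted p under 0.05. Immediate early genes had a median of 0.41, with -0.01 and 0.69 in the first and second experiment (camera adjusted p = 9.1e-12, and adjusted p = 0.78 with an estimated correlation). Ribosomal proteins at a median of -0.03 passed camera (0.036, and adjusted p = 0.84 with an estimated correlation) but were at 0.01 on values as deposited and 0.02 with median centring. Synthetases at -0.06 (0.038 and 0.84), fatty acid synthesis genes at -0.08 (0.036 and 0.78), p53 targets at 0.07 (0.036 and 0.84) and NF-kB genes at 0.10 (0.039 and 0.85) lost their calls with an estimated correlation too. In the blocked fit ribosomal proteins (0.078) and fatty acid synthesis genes (0.068) did not pass. The blocked count was 2 with array weights and 0 without the second low leucine array at 0 min.

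At 480 min against 0 min, single NRF2 target, sterol and chaperone genes were among the rises and single amino acid response and synthetase genes among the falls, while 0 lists passed in the unblocked fit with an estimated correlation. TRIM16 rose by 0.92 ± 0.09 (unblocked, adjusted p = 0.0012), TXNRD1, a thioredoxin reductase, by 0.68 ± 0.08 (0.0036), NQO1, a quinone reductase, by 0.58 ± 0.07 (0.0036) and GCLM, of glutathione synthesis, by 0.51 ± 0.10 (0.04). SQLE, the squalene epoxidase, rose by 0.62 ± 0.07 (0.0031) and MSMO1 by 0.79 ± 0.16 (0.035). DKK1, a Wnt inhibitor, at 0.80 ± 0.16, FSCN1, an actin bundler, at 0.75 ± 0.11, LOXL1 at 0.67 ± 0.10, NR2F1 and TGFBR2 at 0.58, HSPB1 at 0.55 ± 0.11 and SFPQ at 0.54 ± 0.07 rose too. MTHFD2 fell by 0.66 ± 0.09 (0.0073), ASNS by 0.54 ± 0.12 (0.049), PHGDH, which starts serine synthesis, by 0.42 ± 0.09 (0.049), and ATF4 by 0.51 ± 0.09 (0.027). The synthetases YARS1 at -0.47 ± 0.09, CARS1 at -0.44 ± 0.06 and AARS1 at -0.42 ± 0.09 fell, as did HMGB2, BCLAF1, MTIF2, ERI2 and RWDD2B by 0.38 to 0.32.

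Of 35 amino acid response genes 4 fell in the unblocked fit and 19 in the blocked fit, with a median of -0.25 (camera adjusted p = 8.9e-09, and adjusted p = 0.19 with an estimated correlation). Of 17 synthetases 4 and 10 fell, with a median of -0.23 (1.7e-07, and adjusted p = 0.085 with an estimated correlation; blocked 0.05, which before rounding was under the threshold). Of 19 cholesterol genes 4 and 9 rose, with a median of 0.12 (5e-06, and adjusted p = 0.085 with an estimated correlation; blocked 0.033). Of 15 heat shock genes 3 and 7 rose, with a median of 0.12 (1.2e-06, and adjusted p = 0.055 with an estimated correlation; blocked 0.12). Against the 0 min means, cholesterol genes at 480 min were at 0.04 and 0.03 in low leucine in the 2 experiments. In high leucine they were at 0.25 and 0.16. Heat shock genes were at 0.01 and 0.08 in low and at 0.16 and 0.41 in high leucine. These averages over both levels thus also hold the leucine difference at 480 min. Of 19 NRF2 targets 4 and 6 rose, with a median of 0.04 and a mean of 0.14 (0.0015, and adjusted p = 0.25 with an estimated correlation; blocked 0.033). Immediate early genes were at 0.12 (0.0088, and adjusted p = 0.76 with an estimated correlation). Proteasome genes at 0.04 (0.041, and adjusted p = 0.67 with an estimated correlation) and biliary markers at 0.16 (0.029 and 0.12) passed camera in the blocked fit only. Ribosomal proteins were at -0.04 (0.0015, and adjusted p = 0.49 with an estimated correlation) but at 0.02 on values as deposited and with median centring. The unblocked fit called 161 probe sets of 127 genes, 112 higher and 49 lower, and the blocked fit 1460, 865 higher and 595 lower, among them all 161. The blocked fit added CCN2 at 1.23 ± 0.33, PHLDA2 at 0.66 ± 0.06, TXNIP at -0.51 ± 0.07 and PSAT1 at -0.47 ± 0.05. The unblocked count was 106 on values as deposited, 102 without a filter, 95 with 1 probe set per gene, 63 with array weights and 18 without the second low leucine array at 0 min. Within single experiments it was 9 in the first and 682 in the second.

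**Figure D3:**
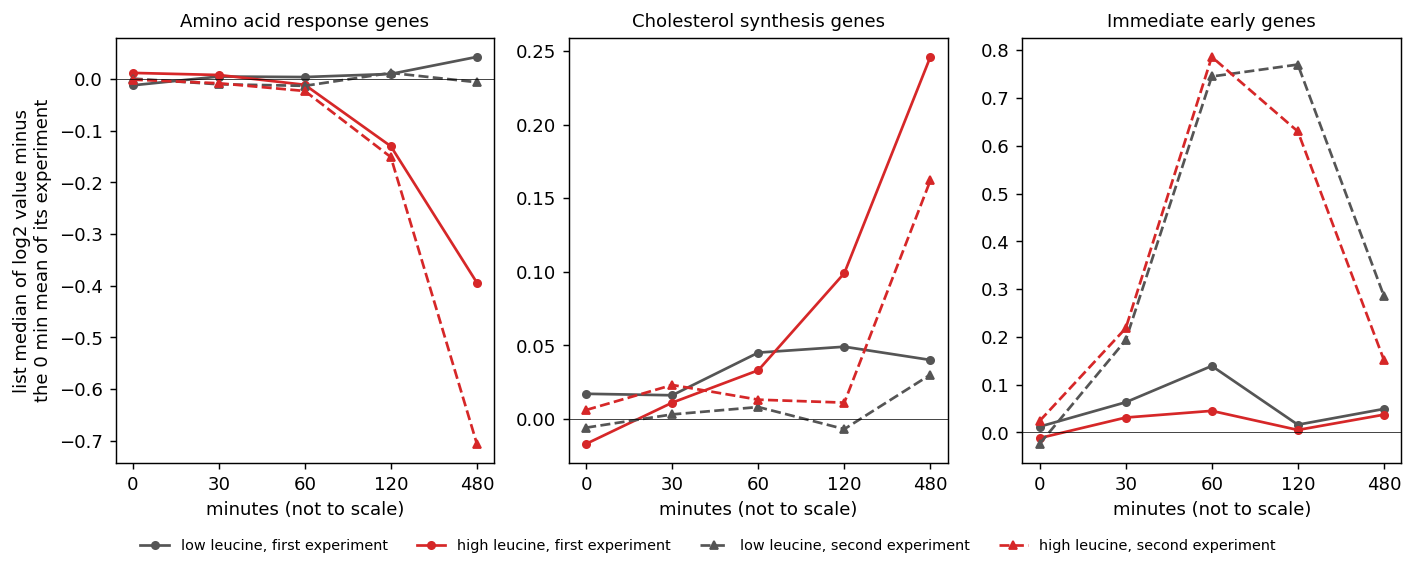
Median over list members of the log2 value minus the 0 min mean of the same experiment, for amino acid response, cholesterol synthesis and immediate early genes, against time in minutes; gray lines are low and red lines high leucine, solid lines the first and dashed lines the second experiment (1 array per point). Amino acid response genes fell below 0 in high leucine in both experiments, and immediate early genes rose in the second experiment at both leucine levels.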

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

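The tests of the 0 min pattern, the tests of the amino acid response pattern other than quantile normalization, and the tests of how immediate early genes changed by experiment and of their starting level were chosen only after the result was seen. The quantile normalization test of immediate early genes was not.

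In the blocked fit the difference between leucine levels differed between times. With the block 86 probe sets passed the interaction over the 4 times together, and against the 0 min difference 43 passed at 30 min, 1 at 120 min and 509 at 480 min. All these counts rest on the 0 min arrays, whose own leucine difference is not resolved. Leucine at 30 min itself gave 0 calls, while 30 against 0 min gave 761 in high and 0 in low leucine with the block. The 43 therefore need not be a leucine difference that arose by 30 min. The values that follow are the 480 min difference minus the 0 min difference in the blocked fit, for the probe set of each gene with the highest signal. Those that passed had an adjusted p from 8.2e-05 to 0.047, and none of them passed in the unblocked fit. Of 35 amino acid response genes 18 passed as more negative and 0 as more positive, with a median of -0.51 (blocked camera adjusted p = 2.7e-18, and adjusted p = 0.063 with an estimated correlation). ASNS at -0.34, ATF3 at -0.52 and SLC7A5 at -0.51 did not pass (adjusted p of 0.22, 0.33 and 0.35). The single genes that follow were drawn from those named for their 480 min difference, which by itself makes such a change more frequent. Only those that passed are given, so that genes named at 480 min such as IFRD1 and LOXL1 are left out. Named genes that were more negative at 480 min were SLC7A11 at -1.22, ATF4 at -1.04, MTHFD2 at -0.80, GFPT1 at -0.72, CEBPG at -0.80, CARS1 at -0.85, STC2 at -1.21, TRIB3 at -1.28, DDIT3 at -0.88, SLC7A1 at -0.82, PMAIP1 at -0.47, CAMTA2 at -1.16 and VEGFA at -1.01. XBP1 at -0.52, HSPA9 at -0.58, COPA at -0.50 and TIMM9 at -0.57 were more negative as well. More positive were TUBA1A at 0.76, IDI1 at 0.51, MSMO1 at 0.90, INSIG1 at 0.85, HSPH1 at 0.53, HSPA2 at 0.46, HSPB1 at 0.82, HSPE1 at 0.58, EIF4E at 0.77 (the call at 120 min was another EIF4E probe set), PRP4K at 0.64, CHPF2 at 0.38, DYNLL1 at 0.45, TMEM14A at 0.50 and NSFL1C at 0.39.

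Some genes named for their 0 min difference passed this test too, and only those are given. They were PIK3C2A at 0.77, HNRNPR at 0.43, RHOA at 0.28, UBBP1 at 0.61, RAD21 at 0.52, NHLRC2 at 0.46, LYPLA1 at 0.59, RPAP3 at 0.56, NEK7 at 0.34, DCAF15 at -0.48, OR1A1 at -0.42, RHOT2 at -0.31, CYTH4 at -0.32 and ACTR5 at -0.34. They were chosen for a large 0 min difference, which by itself makes such a change more frequent.

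For amino acid response genes lower in high leucine at 480 min, the tables argue against several explanations, within the limits given. The list median was -0.43 on values as deposited, which argues against quantile normalization, and -0.38 in the experiment with the weaker difference, which argues against 1 experiment alone. The other probe sets of the list genes had a median of -0.29 and were lower for 9 of 9 genes. The named probe sets of these genes had -0.57. This argues against a probe-level difference such as RNA integrity as the whole source for these genes, while a part stays open. Genes with no other probe set could not be tested. In low leucine the list changed by 0.03 (-0.05 to 0.09) from 0 to 480 min, with 14 of 35 members below 0. Its 480 min medians there were 0.04 and -0.01 in the 2 experiments, against the 0 min means. These argue against a rise of the list there as leucine runs down, although SLC7A11 was at 0.71 and 0.24. In high leucine the list changed by -0.57 (-0.74 to -0.30), with 32 of 35 members below 0. This leaves open a fall in high leucine from a raised starting level. Both ranges resample genes that move together, so they do not measure the spread between arrays. Whether the level at 0 min was raised was not tested, and how the cells were kept before then is not in the labels.

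For the high against low leucine difference at 0 min, the differences of the 2 experiments correlated at 0.327 across probe sets, where leucine at 30 and 60 min, with 0 calls, gave 0.198 and 0.154. The blocked count was 1 without the second low leucine array and 12 without the first high leucine array at 0 min, so a change shared by both experiments and 1 array out of place cannot be told apart. The count was 194 on values as deposited, against quantile normalization as its source. Other probe sets of the same genes moved by only 0.189 of the change of the named ones (0.0536 to 0.326, 19 genes). For the leucine difference at 480 min this was 0.744 (0.657 to 0.842, 98 genes), among calls of matched size, between 0.225 and 0.532. The low ratio at 0 min could come from a probe-level difference such as RNA integrity or labelling, and a change in transcript ends stays open. The ratio cannot decide this, because genes were picked for a call in the named probe set, which by itself lowers the ratio. Matching by size does not match the p-values of the calls at 0 and 480 min. The 0 min arrays are also the reference for every time comparison. In the same range of size the ratio was 0.315 for calls of 60 against 0 min and 0.679 for calls of 480 against 0 min.

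Immediate early genes changed differently in the 2 experiments. This was tested in the separate fit of experiment by time plus leucine level. There the low and high leucine arrays of an experiment at a time serve as its replicates. The p-values thus measure the spread between such arrays and not the spread between experiments. The list rose by 0.67 more in the second experiment at 60 min (camera adjusted p = 3.3e-48, and 0.00021 with an estimated correlation) and by 0.70 more at 120 min (4.3e-56 and 0.00011), with 19 of 35 members past the threshold at each. At 30 min 4 members passed (camera adjusted p = 6.4e-19, and 0.0083 with an estimated correlation). At 480 min 2 passed, and the list call was lost with an estimated correlation (3.5e-05 and 0.11). Levels at 0 min in the first experiment were set against those of the second at 60 min. Over all 35 members they differed by a median of -0.59 (-0.94 to -0.37). This cannot decide whether a raised start was the cause, because 62% of probe sets differed between experiments. A raised start also need not reach the level of the second experiment at 60 min. At 0 min the first experiment differed from the second by a median of 0.21 (-0.02 to 0.32), so levels already raised there stay open. EGR1 was at 10.37 in the first and 9.2 in the second experiment, and FOS at 9.15 and 8.53. Other members went the other way, with CCN2 at 9.23 and 9.58 and HES1 at 9.01 and 9.35. The difference between experiments in the change at 60 min was 0.72 on values as deposited, against quantile normalization. Handling or medium on the day may differ between experiments, but the labels give nothing on either, and no biological explanation was tested.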

How the results depend on the processing

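The blocked fit combined with other choices, the fits without the 0 min arrays and the 30 min reference were chosen only after the result was seen; the other alternatives were planned. Counts are of probe sets past the threshold, and the cause of a change was not tested unless it is given.

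A result was the same if it kept its sign and passed either in both settings or in neither. It was weaker if its call was lost, stronger if a call was gained, and moved if its sign changed without a call. Results that passed in neither setting count as the same, so that number does not measure the share of calls kept. Of the unblocked results for named genes under the alternatives, 7465 were the same, 414 weaker, 143 stronger and 177 moved. Of the blocked ones 6816 were the same, 1002 weaker, 17 stronger and 90 moved. For list results these were 120 the same, 52 weaker and 12 stronger unblocked, and 80 the same, 57 weaker and 2 moved blocked, apart from the reversals given at the end of this part. Single genes were scored over up to 30 alternatives, or 29 with the block. These leave out the additive model, single experiments and single leucine levels, which were scored by counts only. In low leucine arrays alone the unblocked fit called 0 probe sets for 480 against 0 min. TRIM16, TXNRD1, SQLE, NQO1, TGFBR2, SFPQ, MTHFD2 and MTIF2 at 480 against 0 min passed in 30 of 30 alternatives. Between leucine levels at 480 min ATF4, TUBA1A and MTHFD2 passed in 27 and SLC7A11 in 18, but NSFL1C in 9 and TMEM14A and TMSB10 in 7. At 480 against 0 min DKK1 passed in 10, ASNS and PHGDH in 7 and AARS1 in 5, and PMAIP1 passed in 9 for the mean leucine difference. With the block, at 60 against 0 min EGR1 and DUSP1 passed in 11 of 29 and HES1 in 6.

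With an estimated correlation, lists past the threshold numbered 2 for the mean leucine difference, 5 for leucine at 480 min and 0 for 480 against 0 min, and in the blocked fit 2, 4 and 3. With a pseudocount 4 times larger leucine at 120 min gave 0. Values as deposited gave 0 for leucine at 120 min, 15 for leucine at 480 min, 0 for 30 min and 106 for 480 min against 0 min. Median centring gave 0 for the mean leucine difference and 0 at 120 min. Without a filter, where more probe sets are tested, these were 0 and 0, and 480 against 0 min gave 102. With 1 probe set per gene, where fewer are tested, 480 against 0 min gave 95. Array weights gave 20 for leucine at 480 min and 63 for 480 against 0 min.

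The replicate block, which removes the spread between experiments from the error, gave 23 for the mean leucine difference, 77 at 0 min, 4 at 120 min, 545 at 480 min, 86 for the interaction, and 338, 119 and 1460 for 60, 120 and 480 min against 0 min. Without the 0 min arrays leucine at 120 min gave 0 and at 480 min 21. Against the 30 min arrays 480 min gave 150, and 1850 with the block. The mean over 30 to 480 min gave 2, and the additive model 0. Low leucine arrays gave 0, 0 and 0 for 30, 60 and 480 min against 0 min, and high leucine arrays 0 for 30 min. Within the first experiment the mean leucine difference gave 0 and 30, 60 and 480 min against 0 min gave 0, 0 and 9. Within the second experiment the mean leucine difference gave 0, and 30, 60, 120 and 480 min gave 13, 111, 237 and 682.

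Combined with the block, a larger pseudocount gave 46 for leucine at 0 min. Values as deposited gave 194 at 0 min and 39 for 120 against 0 min. Median centring gave 738 for 60 and 273 for 120 against 0 min, no filter 675 and 62, and a filter at the 60th percentile 78 for 60 min. With 1 probe set per gene leucine at 0 and 480 min gave 46 and 343, and 120 and 480 against 0 min 70 and 900. Array weights gave 2 and 330 for leucine at 0 and 480 min, 41 for the interaction, and 21, 2 and 708 for 60, 120 and 480 against 0 min. The mean over 30 to 480 min gave 38 and the additive model 0. Low leucine arrays gave 0, 0, 0 and 31 for 30, 60, 120 and 480 against 0 min, and high leucine arrays 761 for 30 and 36 for 120 min.

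Leaving out 1 array leaves a lone sample that is assumed to vary like the other groups. Unblocked counts then ran from 0 to 1 for the mean leucine difference, 0 to 1, 0 to 0, 0 to 0, 0 to 1 and 0 to 32 for leucine at 0, 30, 60, 120 and 480 min, 0 to 0 for the interaction, and 0 to 1, 0 to 1, 0 to 0 and 18 to 169 for 30, 60, 120 and 480 against 0 min. Blocked counts ran from 11 to 59 for the mean leucine difference, 1 to 100, 0 to 5, 0 to 6, 0 to 9 and 131 to 585 for leucine by time, 18 to 113 for the interaction, and 0 to 6, 1 to 467, 0 to 545 and 580 to 1803 against 0 min. The lowest blocked counts at 60, 120 and 480 against 0 min came without the second low leucine array at 0 min and the highest without the first.

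The median of ribosomal proteins reversed against 0 min, to 0.006 at 120 min and 0.015 at 480 min on values as deposited and to 0.024 and 0.022 with median centring, and in the blocked fit to 0.015 and 0.022 at 480 min. The pseudocount limits what can be seen in probe sets near background.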

Other observations

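No test in this part was chosen after the result was seen, except the values of single immediate early genes and the correlations between experiments.

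FOS, an AP-1 subunit, changed by 0.13 in the first and 2.16 in the second experiment at 60 min, and IER2 by 0.10 and 1.93; both were picked after their values were seen. Across probe sets, the changes of the 2 experiments correlated at 0.507 for leucine at 480 min, 0.414 for 480 against 0 min, and 0.327, 0.198, 0.154 and 0.0422 for leucine at 0, 30, 60 and 120 min. For 30, 60 and 120 against 0 min they were 0.244, 0.209 and 0.254, and 0.342 for the mean leucine difference.

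Other splits of the same arrays were counted for the comparisons with enough arrays. For the mean leucine difference, 14 of 100 splits called as many as the real 1 (highest other 5347), so chance is not excluded. The highest split took 6 more high arrays from one experiment than from the other, which points to the structure by experiment, and 35 splits balanced over experiments called at most 37. With the block 6 of 100 splits called as many as the real 23 (highest other 31), so chance is not excluded there either.

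For times against 0 min the additive model was used. At 30 min 35 of 35 splits called as many as the real 0, with 2756 for the split by experiment. At 60 min 1 of 35 did so (real 1, highest other 0), a share under 0.05 that rests on 1 call and is not taken to exclude chance. At 120 min 3 of 35 did so (real 3, highest other 1359, the split by experiment), so chance is not excluded. At 480 min 2 of 35 did so (real 136, highest other 2007, again the split by experiment), so chance is not excluded by this count, and the remaining splits called at most 1. In the blocked fit the 18 splits are too few for a share under 0.05. There 2 called as many at 30 min (real 1, highest other 7) and 1 each at 60 min (real 139, highest other 3), 120 min (real 20, highest other 3) and 480 min (real 1100, highest other 194).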
